A study of Homo sapiens with 10 samples.

How the data were processed

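Gene expression was measured on 10 Agilent 1-colour arrays of MIAPaCa-2 cells, 5 re-irradiated with 8 Gy and 5 not. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit, amplified and labelled with Cy3 with the Agilent Quick Amp kit. Per the file headers, slides were read in 1 channel and spots were quantified with Agilent Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08. The deposited scanner files hold linear intensity values per spot, among them a mean signal, a local background and a processed signal that the software has background-corrected, per the file headers. Each array had 45015 spots, of which 1639 were controls. Groups were taken from the sample titles and source names.

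The deposited value table holds log2 values for 9510 rows, of which 9506 matched a probe that is not a control. Compared with the scanner files, each of its columns was log2 of the background-subtracted signal (linear r = 1 per array) with a low floor and a factor per array, between -0.27 and 0.081 on the log2 scale. Its columns had medians from 5.52 to 6.55, so over its rows the arrays were neither centred nor equal in median. Its rows cannot show whether whole arrays had been made equal. How its rows were chosen is not given in the sources used here. It was used as an alternative.

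From the processed signal, log2 values were taken, spots marked as non-uniformity or population outliers were left out, and each array's 75th percentile over spots that were not controls was subtracted. Repeat spots of a probe were averaged. Probes were kept if well above background on at least 5 of the 10 arrays, which left 24947 of 41000 probes, and a gene was represented by its probe with the highest mean signal. Of 380 changed genes with more than 1 kept probe, 22 had a probe pointing the other way. Probe accessions and symbols were matched to RefSeq names of assembly GRCh38.p14, used for names only: 27608 of 41000 probes matched and 13392 kept the file's name. Probe positions are those of the files, in hg18. A gene well above background on no array of a group has only a bound there, given as a fold of at least that size. Bounds set the bright group's mean against, for each array, the higher of the probe's own signal and the lowest signal among probes well above background.

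Groups were compared per gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over 18356 genes and a threshold of 0.05. The labels give both groups replicate numbers 1 to 5. Per the file headers, each of 5 slides held 1 array of each group with the same number, scanned in 1 session. The deviations of same-numbered arrays from their group means correlated at 0.28, 0.58, 0.31, 0.60 and 0.62. The highest correlation with another number of the other group was 0.24, 0.24, 0.17, -0.00094 and 0.17, in the same order. Same-numbered arrays thus varied together, but a shared slide and a pairing of the samples cannot be told apart. The fit without the block had been fixed as the main one, and the fit with the replicate number as a block, which is also the slide and scan block, is given where it changes a call or moves a count by over 1.5 times. Adjusted p-values in the text are limma's unless camera is named. No pair of arrays was a duplicate: their median absolute log2 difference was at least 0.149.

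Fixed before the data were examined were 31 gene lists for DNA damage, cell cycle, stress, signalling, metabolism and other cell types, the tests, the alternatives and the rule for naming genes. Lists with at least 5 measured members (29) were tested with camera at its preset correlation of 0.01, and with an estimated correlation and with fry beside it. Named are the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (features without an approved symbol left out), up to 4 called members of each list with the smallest p or, where none was called, up to 2 members as values, and always CDKN1A, MDM2, GADD45A, CCNB1, PLK1, FOS, EGR1, ATM and GDF15. Some genes that the rule takes are not reported here and were not replaced, though they stay in the tests and counts of their lists. This gave 91 genes, of which 82 passed, each in the same direction on all 5 slides. The largest rises and falls have that direction by the rule that their groups did not overlap. VLDLR and RRM2B were named after their values were seen.

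Alternatives were the replicate block, normexp (offset 50) with quantile normalization, quantile normalization of the processed signal, median centring, the value table, other filters on dim probes, the mean of a gene's probes, a trended robust prior, array weights, a plain two-sample test, and leaving out each array. The fit was tested on simulated arrays with the real genes' means, spreads and slide effects (18285 genes, 200 changed, 5 runs). Without the block it recovered 38.5% of genes changed 1.5-fold, 84.5% of those changed 2-fold and 96.1% of those changed 4-fold, and with the block 63.6%, 90.4% and 97.0%. False calls made up 1.49% of calls without the block and 6.28% with it. A simulated list of 20 genes lowered 1.5-fold was called by camera in 5 of 5 runs and an unchanged list in 0. Simulated genes varied independently of each other and with the same spread in both groups. These runs therefore cannot test camera's preset correlation, and the shares of false calls hold for that setting only. In the real data the estimated correlation within a list reached 0.61, for ribosomal protein genes. Figures were drawn with matplotlib 3.10.9. No genome sequence was used here.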

Results

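MIAPaCa-2 is a human pancreatic carcinoma cell line. Cells grown up after an earlier proton irradiation received either a second proton dose of 8 Gy or no second dose, and RNA of the re-irradiated cells was collected 4 h after it. The labels of the cells without a second dose give no time of collection. Transcript levels were measured on 10 Agilent 1-colour arrays, 5 per group. Signal is given as log2 of the processed signal minus the array's own 75th percentile, and positive changes are higher after the second dose. The 75th percentile of the processed signal lay between 629 and 1185, and 58.6% to 64.8% of spots were well above background. No spot was saturated. The number of arrays limits the precision. The sources used here do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which can be technical.

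The comparison asked which transcripts differed between cells 4 h after a second 8 Gy proton dose and cells irradiated only once. Of 25 immediate early and AP-1 genes 22 were lower in the re-irradiated arrays than in the arrays without a second dose, as were 9 of 29 p53 target genes and 7 of 16 genes of the integrated stress and unfolded protein responses, in limma. EGR2, an immediate early zinc finger transcription factor, was 71.9-fold lower, with -3.57 ± 0.51 (SD, n = 5) after re-irradiation against 2.59 ± 1.41 (SD, n = 5) without it. FOS, a component of the AP-1 transcription factor, was 40.4-fold lower (-2.16 ± 0.39 against 3.18 ± 1.69, SD, n = 5 each). Rises were smaller: AMT, the aminomethyltransferase of the glycine cleavage system, was 2.35-fold higher, and SEC31B, a COPII vesicle coat component, 2.18-fold higher. Of 18356 genes tested, 1416 passed an adjusted p of 0.05 in limma, 526 higher and 890 lower after re-irradiation. At least 2-fold differences were found for 431 of them, of which 423 were lower and 8 higher. Differences of at least 4-fold were found for 104 lower genes and for 0 higher genes. The direction was the same on all 5 slides for 1399 of the 1416 genes. For 1189 of the 1416 the groups did not overlap, which fixes the direction on every slide.

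The slide held 1 array of each group with the same replicate number. With the replicate number, and so the slide, as a block, 6289 genes passed, 4131 higher and 2158 lower, and 480 differed at least 2-fold. All 1416 genes called without the block were among them. Without both arrays of replicate 2, 3 or 5 the blocked count was 2873, 3298 and 1491. The median log2 change of all genes was 0.10, and with centring on each array's median it was 0.16. That centring called 1670 genes higher and 877 lower, so 65.6% of its calls were higher, against 37.1% with the 75th percentile. Before scaling, the 75th percentile was 673 to 1185 on control arrays and 629 to 956 on re-irradiated arrays. The median log2 signal of spike-in probes was 9.54 to 10.36 on control arrays and 9.65 to 10.54 on re-irradiated arrays. The calls rest on making arrays equal at the 75th percentile, and scaling to spike-ins was not tested. Across genes, the change rose with signal level, from a median of -0.04 in the dimmest 10% of genes to 0.23 in the brightest 10% (Pearson r = 0.195 across 18356 genes, which are not independent replicates). Small rises of bright genes are of the size of this trend. The 5 values of one group lay wholly beyond the 5 of the other for 2006 genes (10.9%), where chance gives 0.794% if the 10 arrays are exchangeable. That share does not take into account that same-numbered arrays varied together. All control arrays lay at position 1 of their slide and all re-irradiated arrays at position 3, so position and group cannot be told apart. Without control replicate 1 the count of changed genes was 2051 and without control replicate 4 it was 1909; without any other single array it was 680 to 943.

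Among the largest falls were other early growth response factors, EGR4 (-4.33 ± 0.43, log2 fold change ± SE, as for the genes that follow) and EGR3 (-4.23 ± 0.41), the AP-1 member FOSB (-4.16 ± 0.50) and the stress-induced factor ATF3 (-4.49 ± 0.43). NEURL3, a ubiquitin ligase gene, fell by 4.26 ± 0.40. ARL14, a small GTPase gene, changed by -5.50 ± 0.52 and was well above background on 1 of the 5 re-irradiated arrays. ASB2, the protease gene HTRA3, the cytokine gene TNF and the Wnt inhibitor gene SOST were well above background on all 5 control arrays and on none of the re-irradiated arrays. They were at least 8.59-fold, 5.96-fold, 10.1-fold and 5.64-fold lower (adjusted p = 0.000438, 0.000915, 0.00443 and 0.000149), each bound taken against the lowest signal well above background or the probe's own signal where that was higher. With normexp, whose offset shrinks changes of dim genes, 28 of 82 named changed genes had log2 values over 1.5 times smaller and 24 of those still passed, among them ARL14 (-2.47), ASB2 (-1.25), HTRA3 (-1.06), TNF (-1.37) and SOST (-0.95). Others that still passed were GDF15 (-2.10), MDM2 (-0.35), CCNE2 (0.27), H4C1 (-0.65), H2AC6 (-0.99), DCLRE1C (-0.43), WEE1 (-1.10), CCN2 (-1.99), TNFAIP3 (-1.04), CLDN4 (-1.44), LTBP2 (-0.26), CD274 (-0.31) and ITGAM (-0.46). With the mean of the gene's probes TNF lay at -2.81 and LTBP2 at -0.83, and TRIB3 lay at -1.03 in the value table. The bound given for TNF is that of its probe with the highest mean signal, not that of the mean of its 2 probes. The probe for EGR2 lies on chromosome 10, 64241856 to 64241915 (hg18, as the files give it), that for FOS on chromosome 14, 74817967 to 74818026, and that for SEC31B on chromosome 10, 102236403 to 102236462. Adjusted p was 0.000321 for EGR2, 0.00118 for FOS, 0.000386 for EGR3, 0.000386 for ATF3 and 0.000973 for SEC31B.

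The 12 largest rises with groups that did not overlap ranged from 0.83 to 1.27. They were CALML6 (1.27 ± 0.22), AMT (1.23 ± 0.17), SEC31B (1.12 ± 0.13) and C1QTNF12 (1.04 ± 0.18), the hepatocyte growth factor-like gene MST1 (1.03 ± 0.13) and its near-identical copy MST1L (1.03 ± 0.13), TSNAXIP1 (0.96 ± 0.15), the heat shock transcription factor gene HSF4 (0.92 ± 0.14), the base excision repair glycosylase gene NEIL1 (0.91 ± 0.12), PAQR6 (0.84 ± 0.17) and PGGHG (0.84 ± 0.13), and the von Willebrand factor protease gene ADAMTS13 (0.83 ± 0.13). The MST1 and MST1L values are uncertain, since their transcripts could bind each other's probes. CALML6 and TSNAXIP1 were well above background on 4 of the 5 control arrays. Adjusted p in this group ranged from 0.000973 to 0.0161. Each gene was higher on 5 of 5 slides, which follows from choosing genes whose groups did not overlap. In the authors' value table, whose column medians were not equal between arrays, C1QTNF12, PAQR6 and TSNAXIP1 did not pass (adjusted p = 0.0662, 0.165 and 0.0937). The values of CALML6 (0.36), AMT (0.54), C1QTNF12 (0.38), MST1L (0.63), TSNAXIP1 (0.32) and HSF4 (0.46) with normexp and of ADAMTS13 (0.47) with the mean of the gene's probes were over 1.5 times smaller, and each still passed.

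**Figure D1:**
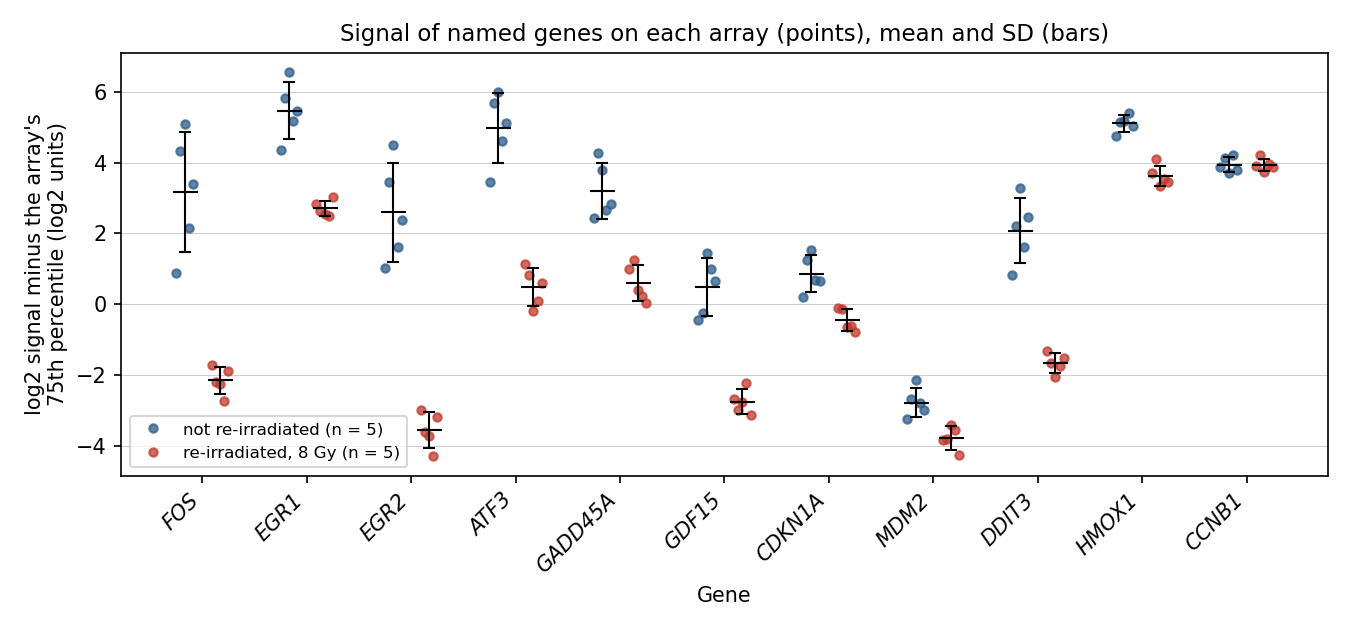
Signal of named genes on each of the 10 arrays, as log2 signal minus the array's 75th percentile (log2 units), with the mean (horizontal line) and SD (error bar) of the 5 arrays of each group. FOS lay at -2.16 ± 0.39 after re-irradiation and at 3.18 ± 1.69 without it, whereas the group means of CCNB1 differed by -0.01.

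Immediate early and AP-1 genes, which growth factors and stress induce within minutes, formed the group with the most members changed. Of 25 members measured, 22 fell, 0 rose and 3 did not pass (23 lower and 0 higher when adjusted over the list alone, 23 and 0 with the replicate block). The list's median change was -1.94, lower on 5 of 5 slides with slide medians from -0.86 to -2.87. Besides those above, EGR1 fell by 2.77 ± 0.32 (SE) and the matricellular gene CCN2 by 3.03 ± 0.35. For the list, camera gave an adjusted p = 8.97e-28, and adjusted p = 0.106 with an estimated correlation. Among NF-kappaB and inflammatory genes, 7 of 15 fell and none rose (9 lower and 0 higher when adjusted over the list alone, 8 and 0 with the replicate block). TNFAIP3, an inhibitor of NF-kappaB signalling, changed by -2.58 ± 0.35 and was well above background on 4 of 5 re-irradiated arrays, the chemokine gene CXCL8 changed by -1.93 ± 0.35 and the cytokine gene LIF by -1.48 ± 0.24. The median of this list was -0.62, and camera gave an adjusted p = 9.89e-07, and adjusted p = 0.277 with an estimated correlation. The NF-kappaB list's median was -1.52 in the value table and -0.23 without the filter on dim probes. The values of these genes were more spread among the control arrays: the median SD over immediate early genes was 0.813 in controls and 0.230 in re-irradiated arrays.

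Of 16 genes of the integrated stress and unfolded protein responses, 7 fell and 1 rose, the lipoprotein receptor gene VLDLR (0.49 ± 0.13; 7 lower and 1 higher when adjusted over the list alone, 7 and 1 with the replicate block). DDIT3, which encodes the stress transcription factor CHOP, was 13.3-fold lower, PPP1R15A, a phosphatase subunit that restores translation, 6.39-fold, CEBPB 3.10-fold and TRIB3 1.57-fold. The list had a median of -0.20, and camera gave an adjusted p = 3.44e-05, and adjusted p = 0.176 with an estimated correlation. The integrated stress list's median was -0.996 in the value table and -0.32 with the mean of the gene's probes. Among NRF2 oxidative stress genes, 5 of 15 fell and none rose (5 lower and 1 higher when adjusted over the list alone, 6 and 2 with the replicate block). They included HMOX1, the haem oxygenase gene (-1.49 ± 0.16), OSGIN1 (-1.81 ± 0.32), the sulfiredoxin gene SRXN1 (-0.57 ± 0.13) and the glutathione synthesis gene GCLC (-0.56 ± 0.13). As a list they did not pass (adjusted p = 0.0812; 0.00233 to 0.478 over the alternatives), but the list was called in 5 alternatives, among them quantile normalization (adjusted p = 0.00387), where its median turned from 0.07 to -0.04, and the fit without re-irradiated replicate 2 (adjusted p = 0.0247). Of 13 heat shock genes 1 fell, the co-chaperone gene DNAJB1 (-1.19 ± 0.23; 1 lower and 0 higher when adjusted over the list alone, 2 and 2 with the replicate block), and the list did not pass (adjusted p = 0.816). Of 17 hypoxia and glycolysis genes 5 fell and none rose, among them the vasoactive peptide gene ADM (-2.29 ± 0.45), ANGPTL4 (-1.77 ± 0.35) and VEGFA (-0.77 ± 0.17) and NDRG1 (-0.59 ± 0.13). That list's median was -0.06 with 6 lower and 0 higher when adjusted over the list alone, 5 and 1 with the replicate block, and camera gave an adjusted p = 0.00460, and adjusted p = 0.447 with an estimated correlation. The hypoxia list's median was -0.10 with normexp, -0.12 with quantile normalization, -0.000692 with centring on the array median, -0.00854 with array weights, -0.028 without control replicate 2, -0.11 without control replicate 4, -0.09 without control replicate 5, -0.23 without re-irradiated replicate 1, 0.00353 without re-irradiated replicate 3, -0.034 without re-irradiated replicate 4 and 0.00760 without re-irradiated replicate 5. Arrays left out singly ended some calls: SRXN1 without re-irradiated replicates 1, 3, 4 or 5 (adjusted p = 0.0552 to 0.0688), GCLC without control replicates 2, 3 or 5 or re-irradiated replicates 3, 4 or 5 (adjusted p = 0.0587 to 0.0704), NDRG1 without re-irradiated replicate 5 (adjusted p = 0.0560) and VEGFA without control replicates 2 or 3 or re-irradiated replicates 3 or 5 (adjusted p = 0.0516 to 0.0546). SRXN1 lost its call in the value table and without the filter on dim probes (adjusted p = 0.111 and 0.0654). GCLC lost its call in the value table, without the filter on dim probes and with the mean of the gene's probes (adjusted p = 0.116, 0.0716 and 0.0759). NDRG1 lost its call in the value table and without the filter on dim probes (adjusted p = 0.103 and 0.0538). VEGFA lost its call with normexp, in the value table and without the filter on dim probes (adjusted p = 0.0518, 0.0712 and 0.0552, with the value -0.46 with normexp). The hypoxia list lost its call in the value table and in fry (adjusted p = 0.100 and 0.168, with the median -0.50 in the value table).

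Of 29 p53 target genes measured, 9 fell, 1 rose and 19 did not pass (13 lower and 1 higher when adjusted over the list alone, 14 and 2 with the replicate block). GDF15, a stress-induced cytokine gene, was 9.47-fold lower, GADD45A, a growth arrest gene, 6.12-fold, PLK3 3.45-fold and SESN2 3.03-fold. The cyclin-dependent kinase inhibitor gene CDKN1A lay at -0.46 ± 0.31 against 0.86 ± 0.52 (SD, n = 5 each; log2 fold change -1.32 ± 0.24, adjusted p = 0.00859), and the ubiquitin ligase gene MDM2 at -3.78 ± 0.33 against -2.78 ± 0.41 (adjusted p = 0.0174). The member that rose was RRM2B, a ribonucleotide reductase subunit gene (0.40 ± 0.11). The list's median was -0.30, lower on 5 of 5 slides with slide medians from -0.05 to -0.56. For the p53 list, camera gave an adjusted p = 1.88e-05, and adjusted p = 0.277 with an estimated correlation. The p53 target list's median was -0.15 with normexp and -1.11 in the value table. In the value table the median of all genes was -0.30.

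Among G2/M and mitosis genes, 2 of 28 fell, the mitotic kinase gene AURKA (-0.83 ± 0.14, adjusted p = 0.00666) and the centromeric histone gene CENPA (-0.78 ± 0.13, adjusted p = 0.00539), and none rose (3 lower and 0 higher when adjusted over the list alone, 9 and 1 with the replicate block). CCNB1 differed by -0.01 ± 0.13 and PLK1 by -0.22 ± 0.17, and neither passed (adjusted p = 0.981 and 0.389). The list's median was -0.21, lower on 5 of 5 slides with slide medians from -0.07 to -0.32, and camera gave an adjusted p = 9.16e-05, and adjusted p = 0.447 with an estimated correlation. The G2/M list's median was -0.13 without control replicate 4. Of 26 G1/S and DNA replication genes 1 rose, the cyclin gene CCNE2 (0.59 ± 0.14), and none fell (0 lower and 1 higher when adjusted over the list alone, 0 and 12 with the replicate block). The G1/S list had a median of 0.22, and camera gave an adjusted p = 0.00406, and adjusted p = 0.520 with an estimated correlation. The G1/S list's median was 0.14 with normexp. Random lists of the same signal levels had a median of 0.18. Of 19 replication-dependent histone genes 12 fell and none rose (16 lower and 0 higher when adjusted over the list alone, 16 and 0 with the replicate block). H2AC6 was 3.66-fold lower, H4C1 2.72-fold, the linker histone gene H1-2 2.11-fold, and H4C8 fell by 1.32 ± 0.20 on the log2 scale, values that are uncertain where near-identical histone genes share a probe's sequence. These are signals of amplified and labelled RNA. How fully the amplification captured histone transcripts was not tested, so the signals need not follow total histone mRNA. The median of the histone genes was -0.50, and camera gave an adjusted p = 2.32e-14, and adjusted p = 0.106 with an estimated correlation. The histone list's median was -0.91 in the value table. The call of CCNE2 was lost without control replicates 2 or 5 or re-irradiated replicates 3, 4 or 5, each left out singly (adjusted p = 0.0599 to 0.0696). CCNE2 lost its call without the filter on dim probes (adjusted p = 0.0772; 0.0195 to 0.0772 over the alternatives). The G2/M list lost its call in the value table and in fry (adjusted p = 0.0803 and 0.168, with the median -0.60 in the value table). The G1/S list lost its call with quantile normalization and in fry (adjusted p = 0.0952 and 0.0521, with the median 0.13 with quantile normalization).

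Few DNA repair genes passed without the replicate block. Of all genes tested 7.71% passed without it and 34.3% with it, so low counts were not particular to repair genes. Of 24 homologous recombination and Fanconi anaemia genes 1 rose, the ubiquitin ligase gene FANCL (0.44 ± 0.11), and none fell (0 lower and 1 higher when adjusted over the list alone, 0 and 4 with the replicate block). Of 13 end joining genes 1 fell, DCLRE1C, the Artemis nuclease gene (-0.69 ± 0.12; 1 lower and 0 higher when adjusted over the list alone, 1 and 5 with the replicate block). Of 19 checkpoint genes 1 fell, the mitotic inhibitor kinase gene WEE1 (-1.73 ± 0.30, adjusted p = 0.00737; 1 lower and 0 higher when adjusted over the list alone, 1 and 4 with the replicate block), and the kinase gene ATM differed by 0.26 ± 0.12 (adjusted p = 0.156). Of 17 excision repair genes 2 rose, NEIL1 and the helicase gene ERCC2 (0.44 ± 0.12; 0 lower and 2 higher when adjusted over the list alone, 1 and 7 with the replicate block). None of these 4 lists passed in camera, with adjusted p = 0.378, 0.969, 0.805 and 0.466. The excision repair list passed in fry (adjusted p = 0.0286; 0.0286 to 0.852 over the alternatives). FANCL lost its call with normexp, with quantile normalization and without the filter on dim probes (adjusted p = 0.0607, 0.0808 and 0.0881). ERCC2 lost its call without the filter on dim probes and with the mean of the gene's probes (adjusted p = 0.112 and 0.0806). DCLRE1C lost its call in the value table (adjusted p = 0.0586; 0.00141 to 0.0586 over the alternatives). Arrays left out singly ended some calls: FANCL without control replicates 2, 3 or 5 or re-irradiated replicates 1, 2, 3 or 5 (adjusted p = 0.0543 to 0.0901) and ERCC2 without control replicates 2, 3 or 4 or re-irradiated replicates 1, 2, 3, 4 or 5 (adjusted p = 0.0501 to 0.109).

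**Figure D2:**
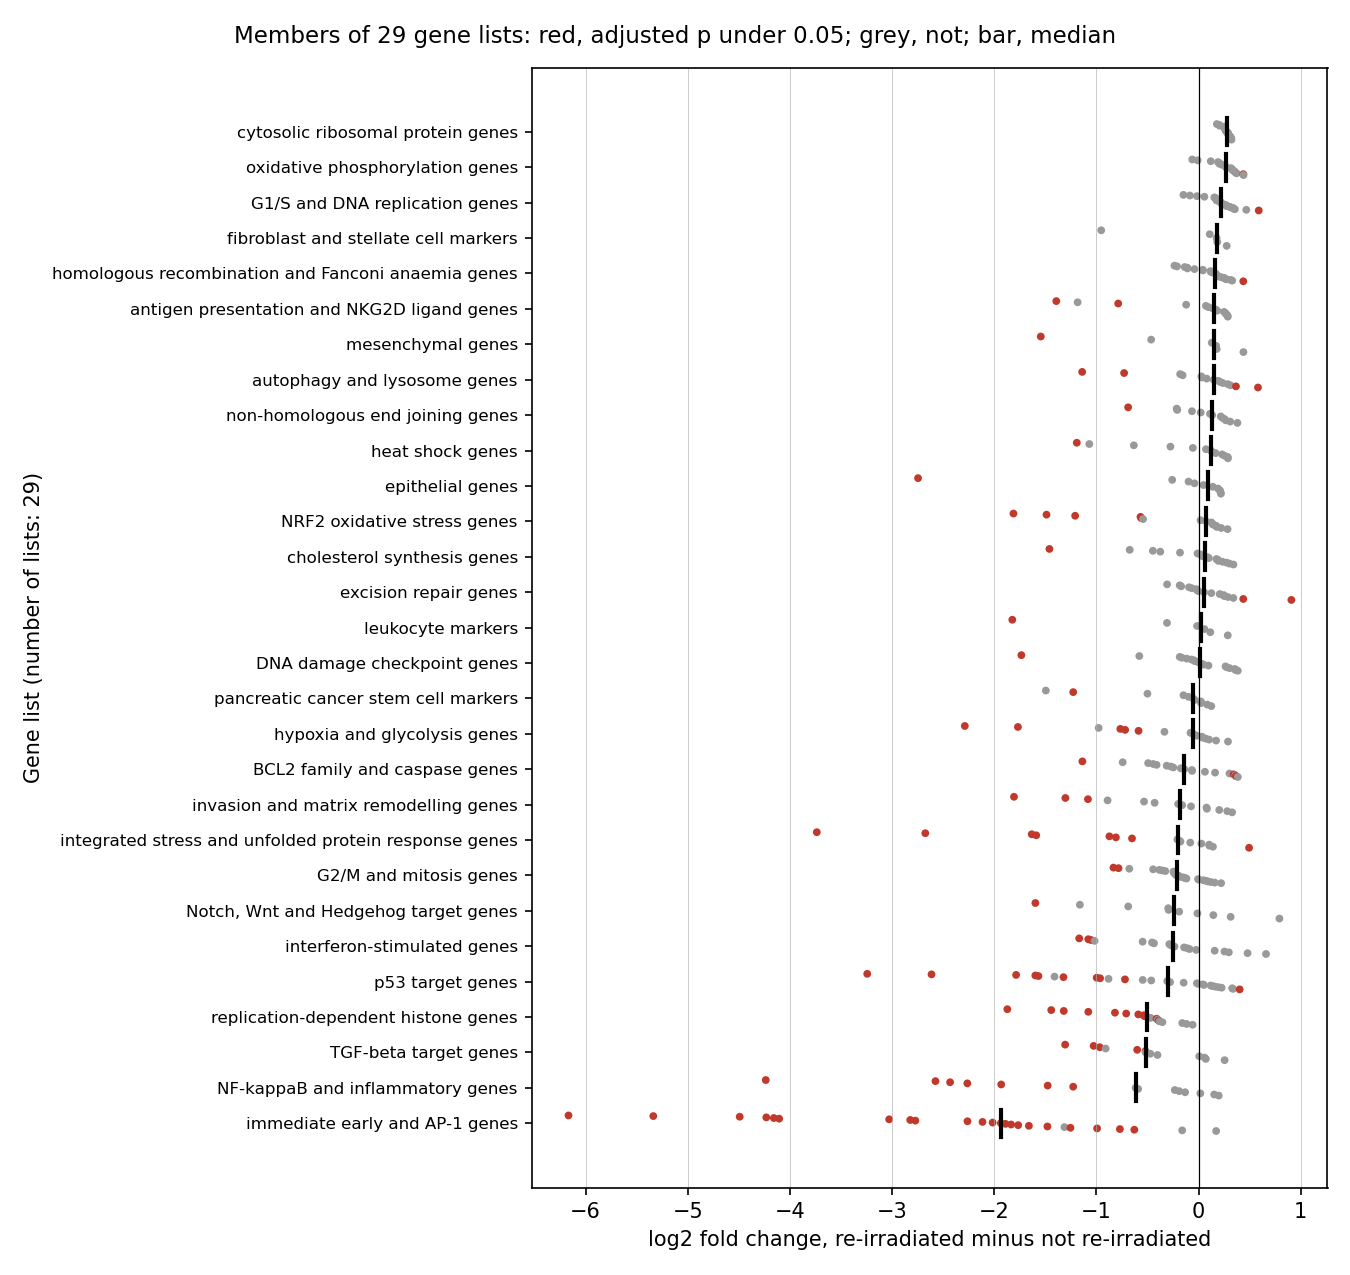
Log2 fold change (re-irradiated minus not re-irradiated, 5 arrays each) of each measured member of 29 gene lists, red where the adjusted p over all genes was under 0.05 and grey where it was not, with the list's median as a black bar. The median of immediate early and AP-1 genes was -1.94 and that of cytosolic ribosomal protein genes 0.28.

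TGF-beta target genes were lower as a list, with a median of -0.52 and 5 of 13 members fallen (6 lower and 0 higher when adjusted over the list alone, 8 and 0 with the replicate block). They included the matrix protein gene TGFBI (-1.31 ± 0.24), SKIL (-0.97 ± 0.22) and PMEPA1 (-0.60 ± 0.14) and LTBP2 (-0.52 ± 0.09), and camera gave an adjusted p = 7.21e-05, and adjusted p = 0.106 with an estimated correlation. Of 20 interferon-stimulated genes 3 fell, IFIT2 (-1.17 ± 0.22), IFIT3 (-1.05 ± 0.24) and OASL (-1.08 ± 0.30), and none rose (3 lower and 0 higher when adjusted over the list alone, 5 and 4 with the replicate block). Their median was -0.25, lower on 4 of 5 slides, and camera gave an adjusted p = 0.00392, and adjusted p = 0.487 with an estimated correlation. The interferon list's median was -0.14 with normexp, -0.38 without control replicate 1, -0.10 without control replicate 2 and -0.15 without control replicate 3. The interferon list lost its call in the value table and in fry (adjusted p = 0.454 and 0.241, with the median -0.44 in the value table). Of 14 invasion and matrix remodelling genes 3 fell and none rose (5 lower and 1 higher when adjusted over the list alone, 6 and 2 with the replicate block). Among them the collagenase gene MMP1 changed by -1.08 ± 0.28 and was well above background on 1 of 5 re-irradiated arrays and 4 of 5 control arrays. MMP1 lost its call with normexp, with quantile normalization, in the value table and without the filter on dim probes (adjusted p = 0.206, 0.0816, 0.104 and 0.0945, with the value -0.12 with normexp). The invasion list had a median of -0.18, and camera gave an adjusted p = 0.0158, and adjusted p = 0.306 with an estimated correlation. The invasion list lost its call with probes well above background on all 10 arrays and in fry (adjusted p = 0.125 and 0.0710, with the median -0.07 with probes well above background on all 10 arrays). The invasion list's median was -0.11 with normexp, -0.93 in the value table, -0.12 without the filter on dim probes, -0.29 with array weights, -0.28 without control replicate 1 and -0.10 without control replicate 3. Among pancreatic cancer stem cell markers 1 of 11 fell, the pluripotency factor gene POU5F1 (-1.23 ± 0.26; 3 lower and 0 higher when adjusted over the list alone, 2 and 0 with the replicate block). These markers had a median of -0.06, and camera gave an adjusted p = 0.0446, and adjusted p = 0.214 with an estimated correlation. The stem cell list's median was 0.00265 with centring on the array median, -0.10 with the mean of the gene's probes, -0.029 without control replicate 1, -0.09 without control replicate 3, -0.09 without control replicate 5, -0.13 without re-irradiated replicate 1 and -0.09 without re-irradiated replicate 4. Among Notch, Wnt and Hedgehog target genes 1 of 10 fell, the Notch target HES1 (-1.60 ± 0.29; 2 lower and 0 higher when adjusted over the list alone, 4 and 1 with the replicate block). For this list the median was -0.24, and camera gave an adjusted p = 0.0360, and adjusted p = 0.214 with an estimated correlation. The stem cell list did not pass without control replicates 1, 2 or 4 or re-irradiated replicate 3 (adjusted p = 0.0610, 0.0601, 0.0804 and 0.0908), nor the Notch, Wnt and Hedgehog list without control replicate 1 or re-irradiated replicates 2 or 3 (adjusted p = 0.0918, 0.0655 and 0.0681). The stem cell list lost its call in the value table, without the filter on dim probes, with probes well above background on all 10 arrays and with array weights (adjusted p = 0.215, 0.0560, 0.112 and 0.0879, with the median -0.44 in the value table, median -0.016 with probes well above background on all 10 arrays and median -0.09 with array weights). The Notch, Wnt and Hedgehog list lost its call in the value table, with probes well above background on all 10 arrays and with the mean of the gene's probes (adjusted p = 0.879, 0.193 and 0.0521, with the median -0.012 with probes well above background on all 10 arrays). The Notch, Wnt and Hedgehog list's median was -0.08 with normexp, -0.12 without the filter on dim probes, -0.12 without control replicate 4, -0.14 without re-irradiated replicate 1 and -0.14 without re-irradiated replicate 3. Arrays left out singly ended some calls: SKIL without control replicates 3 or 5 or re-irradiated replicates 1, 3, 4 or 5 (adjusted p = 0.0591 to 0.0686), PMEPA1 without control replicate 5 or re-irradiated replicates 2, 3 or 5 (adjusted p = 0.0559 to 0.0646), IFIT3 without control replicates 2 or 3 or re-irradiated replicates 1, 3, 4 or 5 (adjusted p = 0.0538 to 0.0609), OASL without control replicates 2, 3 or 5 or re-irradiated replicates 1, 3, 4 or 5 (adjusted p = 0.0815 to 0.105) and MMP1 without control replicates 2, 3 or 5 or re-irradiated replicates 3, 4 or 5 (adjusted p = 0.0678 to 0.0930). SKIL lost its call with normexp and without the filter on dim probes (adjusted p = 0.0508 and 0.0659, with the value -0.36 with normexp). PMEPA1 lost its call in the value table and without the filter on dim probes (adjusted p = 0.106 and 0.0730). LTBP2 lost its call in the value table (adjusted p = 0.135; 0.00255 to 0.135 over the alternatives). IFIT3 lost its call without the filter on dim probes (adjusted p = 0.0613; 0.00809 to 0.0613 over the alternatives). OASL lost its call without the filter on dim probes (adjusted p = 0.113; 0.0139 to 0.113 over the alternatives).

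Cytosolic ribosomal protein genes had a median of 0.28 and oxidative phosphorylation genes of 0.27, higher on 5 of 5 slides in both lists. None of 20 ribosomal protein genes passed over all genes (0 lower and 17 higher when adjusted over the list alone, 0 and 11 with the replicate block), RPL27 with 0.31 ± 0.11 (adjusted p = 0.0906) and RPS23 with 0.32 ± 0.11 (adjusted p = 0.0918). Both passed with the replicate block (adjusted p = 0.0432 and 0.0269) and with centring on the array median (adjusted p = 0.0448 and 0.0462), and their values were 0.10 and 0.09 with normexp. Of 19 oxidative phosphorylation genes 1 rose, the complex III gene UQCRC2 (0.44 ± 0.12), and none fell (0 lower and 10 higher when adjusted over the list alone, 0 and 13 with the replicate block). For ribosomal protein genes camera gave an adjusted p = 7.21e-05, and adjusted p = 0.447 with an estimated correlation, and for oxidative phosphorylation genes camera gave an adjusted p = 0.000209, and adjusted p = 0.277 with an estimated correlation. With normexp the ribosomal list had a median of 0.05 (adjusted p = 0.407). The oxidative phosphorylation list had medians of 0.14 with normexp and 0.13 with quantile normalization and passed in both (adjusted p = 0.00454 and 0.0291). Quantile normalization gave ribosomal protein genes a median of 0.03 (adjusted p = 0.833; 9.41e-06 to 0.833 over the alternatives), below the median of all genes in that setting (0.08). Random lists of the same signal levels had medians of 0.25 for the ribosomal and 0.22 for the oxidative phosphorylation list. The call of UQCRC2 was lost without control replicates 3, 4 or 5 or re-irradiated replicates 1, 2, 4 or 5, each left out singly (adjusted p = 0.0528 to 0.0946). UQCRC2 lost its call with normexp, with quantile normalization and without the filter on dim probes (adjusted p = 0.0748, 0.119 and 0.108).

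The remaining lists did not pass in camera, although single members did. Of 18 cholesterol synthesis genes 1 fell and 0 rose (list adjusted p = 0.696). The repressor gene SNAI1 fell among 6 mesenchymal genes (-1.54 ± 0.35; list adjusted p = 0.604), and the tight junction gene CLDN4 among 10 epithelial genes (-2.75 ± 0.47; list adjusted p = 0.816). Of 19 BCL2 family and caspase genes 1 fell, the anti-apoptotic gene MCL1 (-1.14 ± 0.20), and 2 rose, among them BID (0.34 ± 0.09; list adjusted p = 0.138). Of 14 antigen presentation and NKG2D ligand genes, CD274, which encodes PD-L1 (-1.39 ± 0.25, well above background on 1 of 5 re-irradiated arrays), and the ligand gene MICA (-0.79 ± 0.19) fell (list adjusted p = 0.976). Of 15 autophagy and lysosome genes the cargo receptor gene SQSTM1 (-0.73 ± 0.12) and GABARAPL1 (-1.14 ± 0.25) fell, and the kinase gene ULK1 (0.58 ± 0.10) and LAMP2 (0.37 ± 0.09) rose (list adjusted p = 0.792). Adjusted over the list alone, the numbers lower and higher were 2 and 1 for cholesterol synthesis, 1 and 0 for mesenchymal, 1 and 0 for epithelial, 1 and 2 for BCL2 family, 3 and 1 for antigen presentation and 2 and 3 for autophagy genes. With the replicate block they were 4 and 5, 2 and 1, 2 and 0, 3 and 3, 3 and 5 and 2 and 6, in the same order. Arrays left out singly ended some calls: SNAI1 without control replicates 2 or 5 or re-irradiated replicates 3, 4 or 5 (adjusted p = 0.0504 to 0.0608), BID without control replicates 2, 3 or 5 or re-irradiated replicates 1, 2, 3, 4 or 5 (adjusted p = 0.0767 to 0.103), MICA without control replicates 2, 3 or 5 or re-irradiated replicates 3, 4 or 5 (adjusted p = 0.0534 to 0.0789) and LAMP2 without control replicates 2, 3 or 5 or re-irradiated replicates 1, 2, 3, 4 or 5 (adjusted p = 0.0567 to 0.0876). SNAI1 lost its call without the filter on dim probes (adjusted p = 0.0594; 0.00240 to 0.0608 over the alternatives). BID lost its call with quantile normalization, without the filter on dim probes and with the mean of the gene's probes (adjusted p = 0.115, 0.126 and 0.0738, with the value 0.21 with quantile normalization). MICA lost its call in the value table and without the filter on dim probes (adjusted p = 0.0532 and 0.0747). GABARAPL1 lost its call without the filter on dim probes (adjusted p = 0.0517; 0.00181 to 0.0517 over the alternatives). LAMP2 lost its call without the filter on dim probes and with the mean of the gene's probes (adjusted p = 0.0993 and 0.166, with the value 0.20 with the mean of the gene's probes). The autophagy list passed in fry (adjusted p = 0.0333; 0.0333 to 0.947 over the alternatives), and the antigen presentation list passed as lower in the value table (median -1.34, adjusted p = 0.00183, the lowest of its alternatives).

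Markers of other cell types that a culture could hold were measured only in part. Measured were 6 of 12 leukocyte, 2 of 9 endothelial and 3 of 12 acinar and islet markers. Whether the others were below detection or had no matching probe was not examined. Of 12 fibroblast and stellate markers 5 were measured and none passed, with TAGLN at -0.95 ± 0.28 (adjusted p = 0.0599, 0.0137 with the replicate block) and THY1 at 0.27 ± 0.25 (adjusted p = 0.476; list adjusted p = 0.816). Of 6 leukocyte markers measured, the integrin gene ITGAM fell (-1.82 ± 0.29, well above background on 1 of 5 re-irradiated arrays; list adjusted p = 0.234). Of 2 endothelial markers VWF fell (-0.78 ± 0.18, well above background on 4 of 5 re-irradiated arrays). Of 3 acinar and islet markers none passed, with PTF1A at 0.16 ± 0.17 and INS at -0.08 ± 0.19. INS was well above background on 1 of 5 re-irradiated arrays and on 5 of 5 control arrays. Adjusted over the list alone, 1 marker was lower in each of the fibroblast, leukocyte and endothelial lists and 0 in the acinar and islet list. With the replicate block 1 fibroblast, 2 leukocyte and 1 endothelial markers were lower and 1 leukocyte marker was higher. The call of VWF was lost without control replicate 3 or re-irradiated replicates 1, 2 or 5, each left out singly (adjusted p = 0.0511 to 0.0614). VWF lost its call with normexp, in the value table and without the filter on dim probes (adjusted p = 0.0845, 0.0592 and 0.0608, with the value -0.21 with normexp). TAGLN passed as lower in the value table, with the mean of its probes, with a trended robust prior and with array weights (adjusted p = 0.0226, 0.0430, 0.0474 and 0.0264). The last 2 lists had fewer than 5 measured members and were not tested. In total 15 of 29 lists passed in camera with its preset correlation, 12 lower and 3 higher, the same number as with the replicate block. With an estimated correlation 0 passed at the adjusted threshold and 6 had an unadjusted p under 0.05, and fry called 12. Other splits of the 10 arrays also called lists with the preset correlation, 6 at the median (8 among those that part all 5 pairs) and up to 15. The median and the mean or the test differed in sign for the NRF2, heat shock, cholesterol synthesis, mesenchymal, epithelial, checkpoint, antigen presentation, fibroblast and leukocyte lists.

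Across genes, pairs of control arrays correlated at r = 0.982 to 0.993, pairs of re-irradiated arrays at 0.991 to 0.994, and pairs across the groups at 0.971 to 0.992. The first principal component held 43.7% of the spread and separated the groups, with control arrays from -49.5 to -2.94 and re-irradiated arrays from 21.03 to 35.7. Controls 1 and 4 lay nearest the re-irradiated group, at -2.94 and -6.19. On the second component (16.4%), replicates 1 and 2 of both groups lay above 0 and replicates 3 to 5 below it. The median SD per gene was 0.242 among controls and 0.184 among re-irradiated arrays, and 72.9% of genes had the larger SD among controls.

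**Figure D3:**
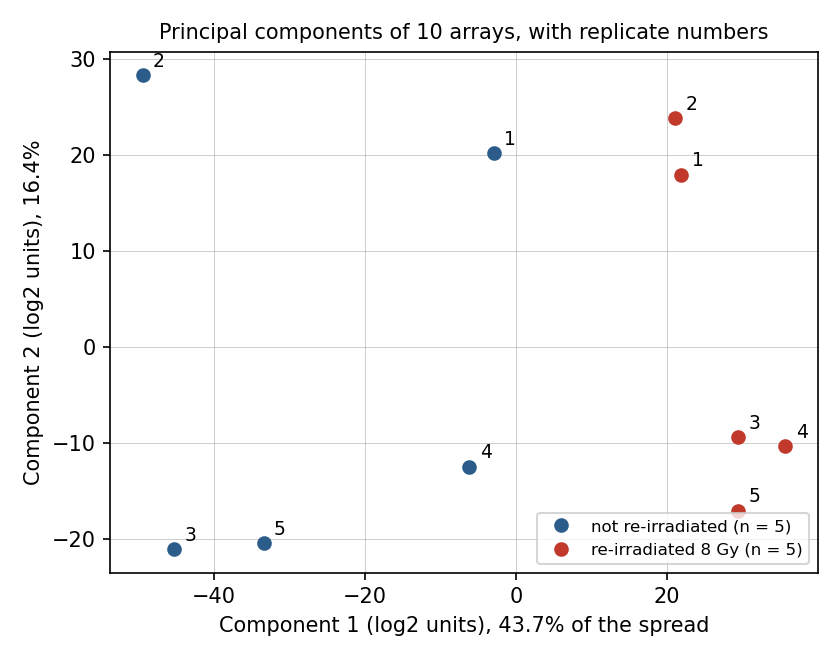
First and second principal components (log2 units) of the 10 arrays over genes without missing values, with replicate numbers beside the points. Re-irradiated arrays lay at 21.03 or above on the first component and control arrays at -2.94 or below.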

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

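Single arrays stood apart from the other 4 of their group, by a gap that as a share of the group's range passed Dixon's critical value for 5 samples, in 14 of 260 sets of values, where chance gives about 1 in 20. All values are log2 signal minus the array's 75th percentile unless stated. Re-irradiated replicate 2 was apart in the highest number of sets: SRXN1 in re-irradiated replicate 2 (3.41, the others 2.91 to 3.05), SKIL in re-irradiated replicate 2 (-3.19, the others -3.80 to -3.75), TAGLN in re-irradiated replicate 2 (-0.75, the others 0.06 to 0.24), the median level of fibroblast and stellate markers in re-irradiated replicate 2 (-0.75, the others 0.06 to 0.24), which is that of TAGLN, and the median level of end joining genes in re-irradiated replicate 2 (0.31, the others -0.18 to -0.10). Also apart were MST1 in re-irradiated replicate 4 (-0.0739, the others -0.49 to -0.37), H4C8 in re-irradiated replicate 5 (-0.17, the others -0.53 to -0.50) and PMEPA1 in re-irradiated replicate 3 (1.91, the others 2.30 to 2.44).

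Among control arrays, single values stood apart for HTRA3 in control replicate 1 (-5.01, the others -2.60 to -1.81), SRXN1 in control replicate 2 (4.02, the others 3.52 to 3.58), RPS23 in control replicate 2 (6.92, the others 7.31 to 7.42), TAGLN in control replicate 3 (1.96, the others 0.45 to 0.89) and the median level of mesenchymal genes in control replicate 3 (1.29, the others 0.31 to 0.58). The median log2 signal of the spike-in probes, before any scaling, was 10.54 on re-irradiated replicate 1 and 9.65 to 9.89 on the other re-irradiated arrays. HTRA3 was well above background on the control array concerned, as on the other 4.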

How the results depend on the processing

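The fits that combine the replicate block with another normalization, or leave out both arrays of a slide, were chosen after seeing the data. Changed genes (1416) numbered 6289 with the replicate block (slide as a block is the same fit, 6289), 7832 with that block and median centring (6005 higher, 1827 lower) and 5180 with that block and quantile normalization (3212 and 1968). They numbered 2547 with median centring, 2634 with array weights, 836 in the value table, which holds 8227 genes, and 717 without a filter on dim probes. Higher genes (526) numbered 4131 with the replicate block, 1670 with median centring, 1252 with array weights, 914 with a trended robust prior, 109 without the filter and 11 in the value table. Lower genes (890) numbered 2158 with the replicate block and 1382 with array weights. Genes changed at least 2-fold (431) numbered 170 with normexp, whose offset shrinks changes of dim genes, and 726 in the value table. Lists shifted (15) numbered 9 in the value table and 0 with an estimated correlation, also with the replicate block (0). The median log2 change of all genes was -0.30 in the value table. The cause was not tested, except that the value table tests fewer genes and its column medians were not equal between arrays. Other processing settings kept these counts within 1.5 times, among them a plain two-sample test of every gene (1478 changed genes).

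Leaving out 1 array in turn gave 680 to 2051 changed genes, 127 to 868 higher, 553 to 1183 lower, 332 to 534 of at least 2-fold and 13 to 15 lists. Changed genes moved by over 1.5 times without any array but control replicates 1 or 4, higher genes without any but control replicate 4, and lower genes without control replicate 3 or re-irradiated replicates 3 or 5 (589, 555 and 553). In the fit with the replicate block, leaving out both arrays of replicate 2, 3 or 5 gave 2873, 3298 and 1491 genes, so that count rests on the slides used. Of the 91 named genes 64 kept direction and side of the threshold in all settings that measured them, and 0 turned direction as a called gene. Without a filter on dim probes, which tests more genes, 19 of them lost their call, and 13 of the 73 that the value table holds did so there. The antigen presentation and NKG2D ligand list turned direction in the value table (median -1.34). With the replicate block, RPL27, RPS23 and TAGLN passed, and it changed no other named gene's and no list's call. Low signal over background limits the dim genes: 23 changed genes were well above background on none of the re-irradiated arrays, and their size is only bounded.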

Other observations

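The tests of exchanged labels and of a state shared with the controls, and the count of lists over splits that part all pairs, were chosen after the result was seen, as were the genes of this paragraph. Several genes outside the fixed lists were among those lower after re-irradiation, with no test of them as a group. They were the nuclear receptor gene NR4A3 (-2.92 ± 0.47, log2 fold change ± SE), the synaptic early gene ARC (-4.05 ± 0.47), the mRNA decay factor gene ZFP36 (-2.80 ± 0.54), the cytokine signalling inhibitor gene SOCS3 (-2.67 ± 0.61), the growth factor gene HBEGF (-2.77 ± 0.49) and the GADD45 family members GADD45B (-3.22 ± 0.44) and GADD45G (-2.23 ± 0.29). The clock repressor gene NR1D1 changed by -2.87 ± 0.30 and the thioredoxin inhibitor gene TXNIP by -1.85 ± 0.26. Each passed with an adjusted p between 0.000553 (NR1D1) and 0.0244 (SOCS3) and was lower on 5 of 5 slides. Among genes that rose were the transcription factor gene CREB1 (0.78 ± 0.12, adjusted p = 0.00387), the ubiquitin ligase subunit gene SKP2 (0.93 ± 0.22, adjusted p = 0.0280) and the glycosyltransferase gene OGT (0.60 ± 0.11, adjusted p = 0.0112), each higher on 5 of 5 slides.

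Immediate early and AP-1 genes were lower in the arrays labelled re-irradiated. A signal-dependent array effect, also one that came with the position on the slide, is argued against as the whole cause, since the list's median of -1.94 lay at percentile 0 of 10000 random lists of the same signal levels (95% of them between 0.05 and 0.24). A cell state that also varied among the control cultures stays open: differences between 2 control arrays correlated across genes with the group difference taken without them at an absolute r of 0.0603 to 0.509, with at least 0.3 in 5 of 10 pairs, against at most 0.149 for re-irradiated arrays, but the r expected without such a state is not known. An exchange of the 2 group labels cannot be told apart from the labelled direction, because lists with a usual response to radiation pointed both ways: the G2/M genes, which usually fall, were lower as labelled (median -0.21, adjusted p = 0.447 with an estimated correlation), and p53 target genes, which usually rise, were lower too (median -0.30, 9 lower and 1 higher of 29, adjusted p = 0.277 with an estimated correlation), among them CDKN1A (-1.32 ± 0.24) and GADD45A (-2.61 ± 0.36). The second dose itself stays open and untested.

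Cytosolic ribosomal protein and oxidative phosphorylation genes had higher medians after re-irradiation. A signal-dependent array effect is consistent with both shifts, since their medians lay at percentiles 79.5 and 93.2 of random lists of the same signal levels, inside the ranges that hold 95% of such lists (0.19 to 0.30 and 0.13 to 0.28). An effect of the second dose on these genes stays open, since a dose effect on bright genes in general would look the same.

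Other splits of the 10 arrays into groups of 5 were fitted for each count, 100 of 126 drawn with the real one. 1 of 100 splits, the real one, gave as many changed genes (1416, the highest other 3). The same held for higher genes (1 of 100, 526 against 3), lower genes (1 of 100, 890 against 3) and genes of at least 2-fold (1 of 100, 431 against 2). Every other split mixes re-irradiated and control arrays in both its groups, so the real difference adds to the spread within them. The low gene counts of the other splits therefore do not measure a rate of false calls. Same-numbered arrays varied together, and most of these splits differ from the real one in keeping some such pairs together. Of the 100 splits, 14 parted all 5 pairs. In all, 16 splits part all 5 pairs, too few for a share under 0.05. Among them the real one gave 1416 changed genes and the highest other 0, and with the replicate block the real one (1 of 16 as large) gave 6289 and the highest other 0. For lists shifted with the preset correlation, 2 of 100 splits gave as many (15, the highest other 15), and 2 of the 16 that part all pairs did (the highest other 15). Other splits called 6 lists at the median, and those that part all 5 pairs 8, so list calls with the preset correlation also arose from other groupings of the arrays.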
